A study of Mus musculus with 4 samples.

How the data were processed

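The data are 4 one-colour Affymetrix arrays of total RNA from mouse peritoneal cells, 1 array per genotype (wild-type or Cebpe-deficient) on each of 2 array types, A and B, which hold different probe sets and so are not replicates. Groups were taken from the sample titles. For the deficient array of type B the title names the deficiency and the RNA source description does not. The labels state 4 mice per genotype, and the text that begins to describe how cells were combined breaks off, so pooling is not described here. Per the labels the mice were of a mixed strain background.

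The deposited values are array intensities on a linear scale, 1 per probe set. They are whole numbers, 20.6% to 29.3% of them below 0, from the values themselves. The software, background correction and scaling the authors used are not given in the sources used here, and detection calls and scanner files were not used here. Gene names came from the platform annotation paired with the probe sets: 7561 probe sets had 1 gene symbol, 224 several and 5394 none. Most of the unnamed ones were on B, where 2001 had 1 symbol and 4567 none, and a probe set with several symbols or none was counted but not named. Of those with 1 symbol, 7544 matched a gene ID of the mouse RefSeq table on assembly GRCm38.p6, and 0 symbols were changed by it. The named probe sets stood for 6137 genes.

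Within each array type the arrays were multiplied to a common mean of the non-control probe sets after leaving out the top and bottom 2% (factors 0.999 to 1.001). The floor was the median of the scaled values of both arrays, 1036.5 on A and 690.17 on B. A probe set above the floor on both arrays gave a log2 ratio, deficient over wild-type. One above it on 1 array gave a bound against the floor, written as at least N-fold, and one at or below it on both gave no ratio. Ratios and bounds of 2-fold or more were counted separately. A gene with several probe sets was read by the measured one with the highest signal relative to the floor. Of the genes, 3132 had a ratio and 617 a bound only.

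With 1 array per genotype and type no test was possible and no p-value is given. The number of arrays limits the precision. Measurement error of 1 ratio was taken as the pooled SD over repeat probe sets of a gene. It was 0.46 below 3 times the floor and 0.34 above, and it holds no spread between mice. Each of 34 gene lists was summarised by the median log2 ratio of its measured genes, placed as a percentile among 10000 random lists of the same size matched on array type and signal (10 bins per type). A list was called apart below percentile 2.5 or above 97.5 with at least 4 measured genes. Bounded genes entered a second median at their bound. The lists held 685 genes, 490 with a named probe set and 322 measured. Named genes were fixed by rule: the 12 highest and 12 lowest ratios among genes whose higher value was at least 2 times the floor, the 6 highest and 6 lowest bounds, Cebpe, and list members with the largest differences or past 2-fold. The lists, rule and design, and all but 3 of the alternatives, were fixed before the data were examined. A few list members with small differences are named beside these for contrast, chosen after their values were seen.

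Alternatives were no scaling, equal medians, quantile, loess (span 0.3) and scaling to the summed bacterial controls, a floor at the 30th or 70th percentile, 3-fold in place of 2-fold, 1 array type at a time, genes in place of probe sets, the mean over a gene's probe sets, unmatched random lists and the list mean. Leaving out suffixed probe sets (family, _g, _r and _i) for counts and lists, and lists on 1 array type, were added after seeing the data.

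The procedure was tested on simulated arrays with this measurement error for the comparison of wild-type with deficient cells over 13069 probe sets. At true folds of 2, 3, 4 and 6, with 50 probe sets each, 46.0%, 94.0%, 100% and 100% were called at 2-fold, against 0.787% of 6103 unchanged ones. Differences were placed only in probe sets at least 4 times the floor on both arrays, and 1 error SD served for all. These rates therefore do not hold for dimmer probe sets, which carry more error. Random lists of 10 unshifted genes were called apart in 5.5% of 400 cases, and lists of 10 genes shifted by -0.5 in 89% of 100 (3328 genes measured). Errors there were drawn independently with the same 1 SD, while the measured ratios had an SD of 0.52 on A and 0.59 on B. The list rates therefore do not carry over to the real lists, whose genes may vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.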

Results

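Total RNA of peritoneal exudate cells from wild-type mice and from mice lacking C/EBPε, a transcription factor of late granulocyte maturation encoded by Cebpe, was hybridised to 2 Affymetrix array types with different probe sets, here called A and B. Cells had been collected by lavage 24 h after an intraperitoneal injection of 2 ml of 4% thioglycollate broth, a sterile irritant that draws neutrophils and then monocytes into the cavity. Per the labels, 4 mice of each genotype aged 6 to 8 weeks were injected, and cytospins of 100 to 200 cells held about 30% monocytes, 60% neutrophils and 7 to 10% lymphocytes in both genotypes. The stated aim was to find possible target genes of C/EBPε in neutrophils and macrophages. Each genotype had 1 array of each type, so 4 arrays in all, and every difference given here has no replicate check. Array type A held 6529 probe sets and type B 6540 besides controls. The arrays of a type ranked their probe sets alike, with a Spearman rho of 0.929 for A and 0.921 for B.

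Cells lacking C/EBPε had lower signal for monocyte and neutrophil chemoattractants, for genes of alternative macrophage activation and for cell cycle genes. Signal of the apolipoprotein gene Apoe was higher. That of Apoc2 was higher by 1 probe set, while its other one was below the floor in both genotypes. Of 19 measured cytokine and chemokine receptors, 4 were higher and 4 lower by 2-fold or more. Ccl7 and Ccl2, which attract monocytes, were 8.27-fold and 5.02-fold lower than in wild-type cells, and Arg1, the arginase of alternatively activated macrophages, was 6.31-fold lower. Apoe, an apolipoprotein that macrophages secrete, was 4.64-fold higher, and Hsd11b1, which regenerates active glucocorticoid, was 6.41-fold higher. With the floor at the 70th percentile, Hsd11b1 and Ccl7, each below that floor in 1 genotype (854 and 1099), had log2 bounds of 1.42 and -2.15 in place of ratios of 2.68 and -3.05. Of 5903 probe sets above the signal floor on both arrays of their type, 200 were higher and 204 lower by 2-fold or more in the deficient cells, so 49.5% of these were higher. A further 152 higher and 120 lower had a bound of 2-fold or more, being above the floor in 1 genotype only. Scaling to the bacterial hybridisation controls moved the median of all measured probe sets by 0.20 log2 units on A and 0.35 on B and gave 488 higher and 110 lower, 81.6% of them higher (154 and 55 on A, 334 and 55 on B). Equal medians turned the balance on each type, from 75 higher and 93 lower to 95 and 78 on A, and from 125 and 111 to 89 and 170 on B. Repeat probe sets of the same gene gave a measurement error of 0.38 log2 units (SD, 424 genes). Normally distributed error of that size alone would put about 45.8 probe sets past 2-fold. It takes 1 SD for all probe sets, so it understates dim ones, whose SD below 3 times the floor was 0.46.

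**Figure D1:**
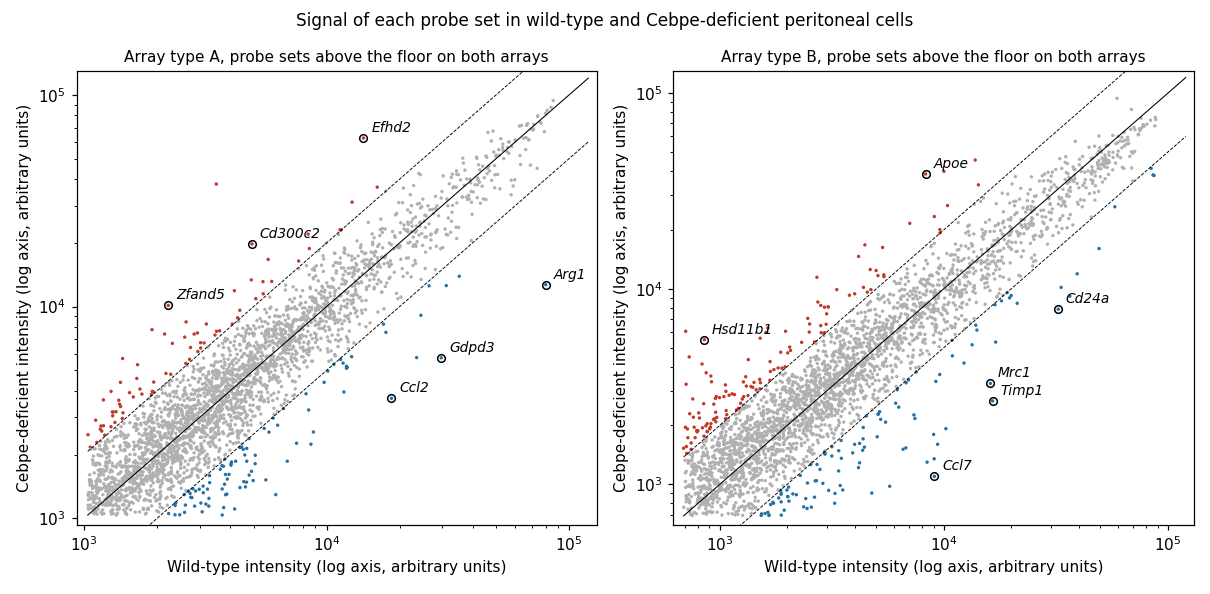
Intensity of each probe set above the floor on both arrays, wild-type on the x axis and Cebpe-deficient on the y axis (both log axes, arbitrary units), for array types A and B. The solid line marks equal signal and the dashed lines 2-fold differences; 75 red and 93 blue points on A, and 125 red and 111 blue points on B, are 2-fold or more higher or lower in deficient cells, and Ccl7 and Arg1 lie far below the lines.

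Among the genes with the lowest ratios, Arg1 read 80067 in wild-type and 12695 in deficient cells. Timp1, an inhibitor of matrix metalloproteinases, was 6.19-fold lower, Ctse, the aspartic protease cathepsin E, 6.49-fold lower and Mrc1, the macrophage mannose receptor, 4.92-fold lower. Acod1, which makes itaconate in activated macrophages, was 5.86-fold lower on B, and its measured probe set on A had a log2 ratio of -1.38. Il1r2, the decoy receptor for interleukin 1, was 5.29-fold lower, the neutrophil chemoattractant Cxcl2 4.41-fold lower and the surface glycoprotein Cd24a 4.13-fold lower. Gdpd3, a phosphodiesterase of lysophospholipids, and Plxnd1, a semaphorin receptor, completed the 12 lowest genes at 5.19-fold and 4.77-fold. With the floor at the 70th percentile Ctse, Il1r2 and Plxnd1 had log2 bounds of -2.04, -1.22 and -1.27 in place of ratios. Among genes above the floor only in wild-type cells, Mxd1, a repressor that pairs with MAX, was at least 8.30-fold lower. Alas2, the erythroid enzyme of haem synthesis, was at least 6.92-fold lower, the AP-1 gene Fosl2 at least 6.23-fold, Grwd1 at least 6.12-fold, G0s2, an inhibitor of triglyceride lipase, at least 5.90-fold and the transcription factor Egr2 at least 5.73-fold. With the floor at the 70th percentile the log2 bounds were -1.49 for Mxd1, -1.23 for Alas2, -1.07 for Fosl2 and -1.31 for Grwd1, and those of G0s2 and Egr2 (-0.95) were under 2-fold.

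Among the highest ratios, Apoe was higher on both array types, with log2 ratios of 2.21 on B and 3.43 on A, both from probe sets of the type shared within a gene family. Apoc2, the apolipoprotein that activates lipoprotein lipase, was at least 17.2-fold higher by 1 such probe set, while its other probe set was below the floor in both genotypes. Zfand5 was 4.55-fold higher, the receptor gene Cd300c2 4.02-fold, the kinase gene Jak3 3.94-fold, Mapk7, which encodes ERK5, 3.71-fold and Cic, a transcriptional repressor, 3.68-fold. Znrf1, a ubiquitin ligase, was 3.20-fold higher, the metalloproteinase inhibitor Timp2 3.11-fold and the interferon-inducible Ifi209 3.10-fold. With the floor at the 70th percentile Jak3 and Znrf1 had log2 bounds of 1.15 and 1.06 in place of ratios, and Ifi209, with a bound of 0.78, was under 2-fold. Probe sets of Efhd2, a calcium-binding protein, disagreed, with log2 ratios of 2.14 and -0.17, and those of the lysosomal membrane protein Gpr137b gave 2.03 and 0.68. Among genes above the floor only in deficient cells, Cela1 was at least 6.35-fold higher. The nuclear receptor genes Rxrb and Rxra, with log2 bounds of 3.58 and 2.34, Dmwd at 2.43 and Fgf15 at 2.17 were also in this class, and their wild-type readings were below 0 (-3287, -1337, -1808 and -1324). With the floor at the 70th percentile Rxra, Dmwd and Fgf15 were under 2-fold (0.77, 0.86 and 0.87), and the bounds of Apoc2, Rxrb and Cela1 were 2.54, 2.01 and 1.10.

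Of 34 gene lists fixed before the data were examined, 31 had 4 or more measured genes. The medians of 12 lay beyond the middle 95% of random lists matched on signal, 11 of them lower and 1 higher, against 1.55 that chance would give. Lists share genes, so these are not separate pieces of evidence. The 1.55 holds only if genes vary independently, and genes of a list may vary together between any 2 samples. The count of 12 is therefore no measure of an excess over chance.

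**Figure D2:**
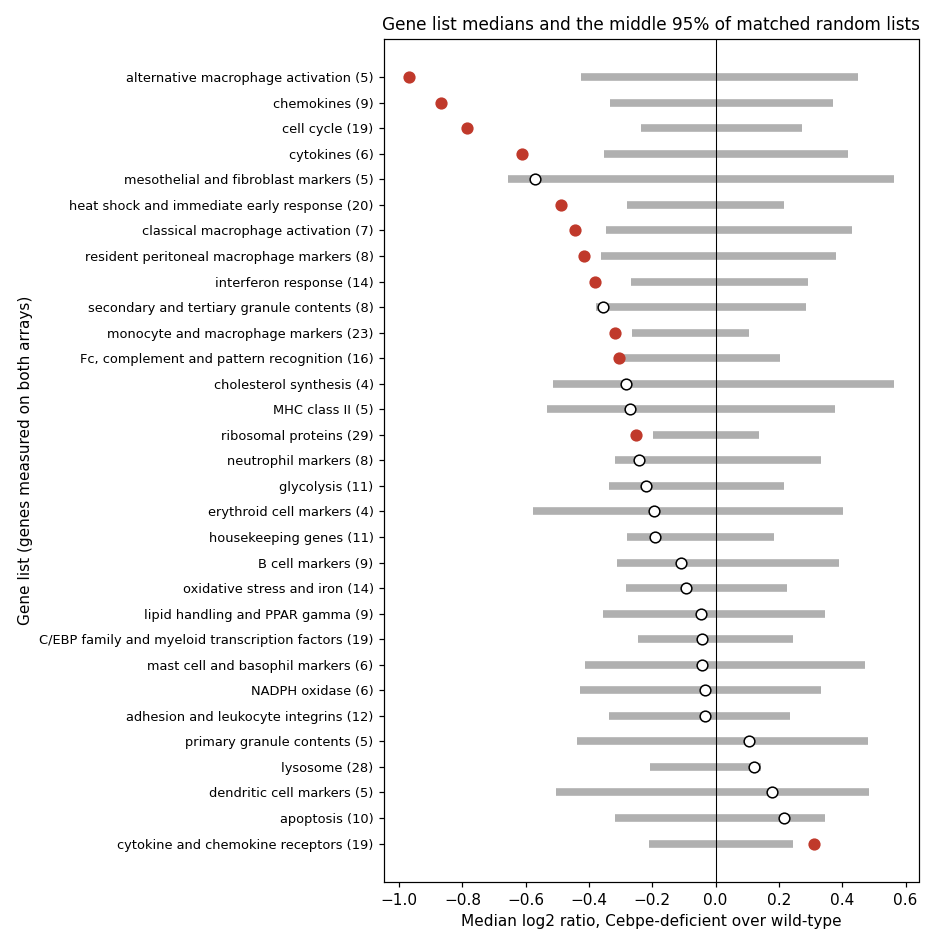
Median log2 ratio (deficient over wild-type, x axis) of each gene list with 4 or more genes measured on both arrays (number in parentheses, y axis). Grey bars span the middle 95% of the medians of 10000 random lists matched on signal, and filled points are the 12 lists beyond them, from alternative macrophage activation at -0.97 to cytokine and chemokine receptors at 0.31.

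All 9 measured chemokine genes were lower in deficient cells, with a median log2 ratio of -0.87 that lay below each of the 10000 random lists (percentile 0). Besides Ccl7, Ccl2 and Cxcl2, at -3.05, -2.33 and -2.14, this held for Ccl3 at -0.96, Ccl6 at -0.87 and the interferon-induced Cxcl10 at -0.73. Cxcl1 was above the floor in wild-type cells only, and the median with it at its bound was -0.80. All 6 measured cytokine genes were lower as well (median -0.61, percentile 0.19; -0.45 with 4 bounded genes), among them Il1rn, the interleukin 1 receptor antagonist, at -1.34, Il1b at -1.11 and Tnf at -0.39. A second probe set of Tnf, on A, had a ratio of 0.15. Csf1, the macrophage growth factor, was at least 2.97-fold lower. Of the 7 measured classical activation genes, which share Cxcl10, Il1b and Tnf with these lists, 5 were below 0 (median -0.44, percentile 0.865; -0.39 with bounds). That list came back inside the random range with a floor at the 30th percentile (percentile 2.70) or the 70th (2.62).

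Alternative activation genes were lower as well (5 of 5 below 0, median -0.97, percentile 0.015). Arg1 and Mrc1 stood at -2.66 and -2.30, Il4ra, a chain of the interleukin 4 receptor, at -0.97, and Chil3 and Tgm2 at -0.37 and -0.14. Resident peritoneal macrophage markers were lower in 7 of 8 cases (median -0.42, percentile 1.37), led by Serpinb2, an inhibitor of plasminogen activators, at -1.68 and Gata6, their transcription factor, at -0.79. On A alone their percentile was 4.48.

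The general monocyte and macrophage markers went both ways. Of 23 measured, 15 were below 0 and 8 above (median -0.32, percentile 0.29; -0.25 with 1 bounded gene). Mrc1, the lipopolysaccharide co-receptor Cd14 at -1.03 and the complement genes C1qa at -0.89 and C1qb at -0.80 were at the lower end. Apoe, the chemokine receptor gene Ccr2 at 0.97, Csf1r, the receptor of macrophage colony-stimulating factor, at 0.84 and Mpeg1 at 0.66 were at the upper end. Their mean, -0.20, had a percentile of 11.2, and the median left the tail with a floor at the 30th percentile (3.07), without suffixed probe sets (10.7) and on A alone (25.9). Fc, complement and pattern recognition genes overlapped with these. The scavenger receptor Msr1 stood at -0.87 and -1.58 by its probe sets, and C3ar1 at 0.98. Of 16 measured genes of this list, 11 were below 0 (median -0.31, percentile 2.11, and -0.14 with 3 bounded genes). Of 13 alternatives 7 put them within the random range: quantile (4.97), loess (5.48) and bacterial-control (5.61) scaling, a floor at the 70th percentile (3.0), the list mean (5.74), no suffixed probe sets (15.1) and A alone (14.9). Under bacterial-control scaling the medians of both lists turned above 0, to 0.03 and 0.04. Relative to the median of all genes under that scaling they stayed below 0.

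Secondary granule genes are known targets of this factor in maturing neutrophils. Of 8 measured secondary and tertiary granule genes, 5 were below 0 (median -0.36, percentile 3.12, and -0.34 with 3 bounded genes), which is inside the random range. Quantile scaling put the percentile at 1.82. Over the alternatives the median ranged from -0.43 to 0.04 and the percentile from 1.82 to 53.55. Ngp, neutrophilic granule protein, was 2.97-fold lower, Mmp9 stood at -0.62, Lcn2, the iron-siderophore binder, at -0.52 and -0.72 by its probe sets, and Slpi, Hp and Slc11a1 at 0.45, 0.55 and 1.10. Ltf, lactoferrin, read 722 and 210, near the floor, and Camp was below the floor in both genotypes. Primary granule genes had a median of 0.10 (5 genes, percentile 72.0), with Mpo at 0.36 and Elane at 0.11. NADPH oxidase genes had a median of -0.03 and a mean of 0.13 (6 genes, percentile 59.2), and quantile, loess and bacterial-control scaling turned that median above 0.

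Of 8 measured neutrophil markers, 7 were below 0. The calcium-binding genes S100a8 and S100a9 stood at -0.08 and -0.24, and Itgb2 stood at -0.15. Csf3r, the receptor of granulocyte colony-stimulating factor, was at -1.31, Ly6g at -1.44 and Il1r2 at -2.40, while Cxcr2 was at least 2.05-fold lower and Mxd1 at least 8.30-fold lower. The median was -0.24 (percentile 6.42), or -0.64 with the 2 bounded genes. Their mean of -0.66 had a percentile of 0.09, and the median reached percentile 0 with a floor at the 30th percentile and 0.49 on B alone.

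Cytokine and chemokine receptors were the only list above the random range, with a median of 0.31 (percentile 99.2; 0.18 with 4 bounded genes), with 12 of 19 measured genes above 0. Tnfrsf1b, the second receptor for TNF, was 2.91-fold higher, with 1.53 by its second probe set, and Ifngr1, Csf2rb2 and Il10ra, chains of the receptors for interferon gamma, interleukin 3 and interleukin 10, stood at 1.45, 1.13 and 1.06. Besides Il1r2 and Csf3r, the chemokine receptors Ccr3 and Ccr1 were lower at -1.92 and -1.40. The list's mean was 0.07 (percentile 69.0). Its median had a percentile of 67.9 with a floor at the 30th percentile, and on B alone it was -0.06.

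Cell cycle genes were lower in 16 of 19 cases (median -0.78, percentile 0; -0.52 with 7 bounded genes), 8 of them by 2-fold or more. Ccne1 and Mki67 stood at -1.54 and -1.53, the replication helicase genes Mcm6 and Mcm7 at -1.33 and -1.30 and Cdk1 at -1.18, whereas Cdk2 was at 1.08. Heat shock and immediate early genes were lower in 18 of 20 cases (median -0.49, percentile 0.04), with Hsp90aa1 at -1.19, Hspe1 at -1.10, Hsph1 at -1.04 and Fos at -0.80. Interferon response genes had a median of -0.38 (11 of 14 below 0, percentile 0.35; -0.49 with 5 bounded genes). Among them Psmb8, an immunoproteasome subunit, was at -0.84, Gbp2 at least 3.31-fold lower and Ly6e at 0.47. On A and on B alone the interferon percentile was 7.02 and 8.23. Ribosomal protein genes were slightly lower (25 of 29 below 0, median -0.25, percentile 0.195), with Rps26 at -1.21. Without suffixed probe sets their median was 0.02 (percentile 46.7), and on B alone the percentile was 20.7. Bacterial-control scaling turned the ribosomal median to 0.06, which was still below the median of all genes.

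The remaining lists lay inside the random range. Lipid handling genes had a median of -0.05 and a mean of 0.02 (9 genes, percentile 45.9). Besides the higher Apoe, the fatty acid carrier Fabp4 stood at -1.43 and the lipase gene Lpl at -0.91. Its sign turned under quantile, loess and bacterial-control scaling. C/EBP family and myeloid transcription factors had a median of -0.04 and a mean of 0.04 (19 genes, percentile 39.1), turning positive under median and bacterial-control scaling, with Cebpa at -0.08, Cebpb at 0.25, Cebpd at -0.38 and Klf2 at 1.02. Lysosomal genes had a median of 0.12 (28 genes, percentile 95.9), with Man2b1 at 0.92 and Ppt1 at 0.89, and lay above the random range by their mean (0.17, percentile 98.8), with the mean of a gene's probe sets (97.6), under bacterial-control scaling (97.54) and on A alone (98.7). Adhesion genes had a median of -0.03 and a mean of -0.19 (12 genes, percentile 63.6), the median turning above 0 under quantile, loess and bacterial-control scaling. Apoptosis genes stood at 0.22 (10 genes, percentile 88.6), cholesterol synthesis at -0.28 (4 genes, 12.2), glycolysis at -0.22 (11 genes, 16.0) with the glucose transporter Slc2a1 at -1.25, and oxidative stress and iron genes at -0.09 (14 genes, 31.7) with Txnrd1 at -1.06. Medians with bounded genes were -0.05 for lipid handling, -0.04 for the transcription factors, -0.03 for adhesion, 0.21 for apoptosis and -0.06 for oxidative stress.

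Markers of other cells lay inside the random range, with medians below 0 except for dendritic cells. The dendritic median, 0.18, went as low as -0.23 among the alternatives. B cell markers had a median of -0.11 (5 of 9 genes below 0, percentile 18.7; -0.24 with bounds), with Ighm at -0.50 and Ms4a1 at 0.48 and -0.30 by its probe sets, and MHC class II genes one of -0.27 (5 of 5 below 0, percentile 16.1; -0.19 with bounds). Mast cell and basophil markers had a median of -0.04 (6 genes, percentile 37.4; -0.14 with bounds) and dendritic cell markers 0.18 (5 genes, percentile 74.4; 0.18 with bounds), with the actin-bundling Fscn1 at -1.18. In the erythroid list (4 genes, median -0.20, percentile 31.0; -0.20 with bounds) the beta-globin gene Hbb-b2 was 3.08-fold lower while the alpha-globin gene Hba-a1 stood at 0.04 and -0.46 by its probe sets. Mesothelial and fibroblast markers had a median of -0.57 (5 of 5 below 0, percentile 3.73; -0.38 with 1 bounded gene), with Col3a1 and Sparc at -1.70 and -1.51. Of 10 alternatives 5 put this list below the random range: a floor at the 30th percentile (percentile 0.06), bacterial-control scaling (0.025), unmatched random lists (1.49), the list mean of -0.82 (0.82) and B alone (0.28). The T and NK cell, eosinophil and megakaryocyte lists had 2, 1 and 0 measured genes and no median. The measured T and NK cell genes Gzma and Cd247 were at -0.66 and -0.20, and the measured eosinophil gene Ccr3 was at -1.92. Housekeeping genes had a median of -0.19 and a mean of -0.06 (11 genes, percentile 21.2), above 0 under quantile, loess and bacterial-control scaling. Under bacterial-control scaling the medians of the B cell, MHC class II, mast cell, erythroid, oxidative stress and glycolysis lists also turned above 0.

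Log2 ratios of the same gene on A and B correlated across 163 genes (204 pairs of probe sets) with Pearson r = 0.53 and Spearman rho = 0.49, genes not being independent replicates. Each pair of probe sets of a gene, within or between array types, was then read in both directions. Of 61 such readings with the first probe set past 2-fold, 50 had a partner of the same sign. In 14 the partner was past 2-fold in that direction as well. A probe set with several partners counts once per partner, and a pair with both past 2-fold counts from each side. Ratios of 3' to 5' probe sets of Gapdh and Actb lay between 0.758 and 0.893 on the 4 arrays. The Gapdh controls had a mean log2 ratio of -0.03 on A and -0.22 on B, and those of Actb 0.13 on A and -0.19 on B. The values on B, and that of Gapdh on A, turned above 0 under bacterial-control scaling, and Gapdh on A also under median and loess scaling. No probe set was named Cebpe, so the level of the targeted gene was not analysed here.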

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

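Leaving out suffixed probe sets, and running lists on 1 array type, were chosen after seeing the data. Of the alternatives for the 12 lists apart, 131 left the list apart in the same direction, 20 put it inside the random range and 1 turned it. Chemokines, cytokines, alternative activation, cell cycle and heat shock genes stayed apart under each alternative run. No scaling, equal medians and bacterial controls shift all ratios of an array type alike. These alternatives therefore left a list's place among random lists less room to move, though some lists crossed the bounds. Bacterial-control scaling took mesothelial and fibroblast markers from percentile 3.73 to 0.025. It also put Fc and complement genes inside the random range and lysosomal genes above it. Of the 36 named genes, 30 were 2-fold or more under every scaling and floor and 6 (Ifi209, G0s2, Egr2, Dmwd, Rxra and Fgf15) were not, each with the floor at the 70th percentile. Of 252 values for them 0 changed sign, which says little, since these genes were picked for the largest ratios and bounds. For the lists not apart, 210 alternatives left them inside the random range and 13 put one beyond it, which concerned neutrophil, mesothelial, lysosomal and secondary granule genes. Ratios of dim probe sets carry more error, with an SD of 0.46 below 3 times the floor and 0.34 above.

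Where not stated, the cause was not tested. Ratios of 2-fold or more, higher then lower, numbered 488 and 110 under bacterial-control scaling (bounds higher 230), 660 and 630 with the floor at the 30th percentile (bounds 497 and 474) and 76 and 67 at the 70th (bounds 25 and 32). By construction, stricter or narrower counts were smaller: 38 and 49 at 3-fold (bounds 55 and 44), 75 and 93 on A (43 and 52), 125 and 111 on B (109 and 68) and 94 and 114 by gene (61 and 56). Leaving out suffixed probe sets gave 159 and 152. The correlation between array types was 0.31 with the floor at the 30th percentile and 0.62 at the 70th.

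List medians inside the random range were, for Fc and complement genes, -0.21 under quantile, -0.21 under loess, 0.045 under bacterial-control scaling, -0.31 with the floor at the 70th percentile, -0.26 as a mean, and -0.14 without suffixed probe sets and on A. For monocyte and macrophage markers they were -0.25 with the floor at the 30th percentile, -0.20 as a mean, -0.12 without suffixed probe sets and -0.046 on A. Classical activation gave -0.39 and -0.44 at the 30th and 70th percentile floors. Receptors gave 0.062 at the lower floor, 0.068 as a mean and -0.056 on B, where the place among random lists turned. Resident macrophage markers gave -0.36 on A, interferon genes -0.20 on A and -0.40 on B, and ribosomal genes 0.016 without suffixed probe sets and -0.24 on B. Alternatives for a Cebpe probe set were not run because none was named, and no array could be left out. No paired analysis was possible because each genotype has 1 array per array type.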

Other observations

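The tests in this part were chosen after the ratios were seen, except that of the genes next to Cebpe, which was set before those genes were looked at. Most measured core subunits of the proteasome, the barrel-shaped protease that degrades ubiquitin-tagged proteins, were lower in deficient cells. Among 54 groups of 6 or more measured genes sharing a symbol stem, 6 lay beyond the middle 95% of random lists. Chance would give 2.70 if the genes of a group varied independently. The 9 Psmb genes had a median log2 ratio of -0.54 (percentile 0.36), with Psmb10 at -1.66. Psmb8, at -0.84 and -0.13 by its probe sets, and Psmb9 are also in the interferon list. The 6 Psma genes had a median of -0.56 (percentile 0.39), with Psma4 at -1.05 and Psma7 at 0.18. The 10 Psmd genes of the regulatory particle lay inside the random range (median -0.17, percentile 11.5). The 8 measured Cct genes, subunits of the chaperonin that folds actin and tubulin, had a median of -0.51 (percentile 1.07), with Cct6a at -1.78 and Cct3 at -1.16. The 6 Eef genes, translation elongation factors and the kinase gene Eef2k, had a median of -0.41 (percentile 1.75), with Eef2k lowest at -0.96. Eef1a1, at -0.26 on B, had ratios from -0.40 to 0.03 by its probe sets on A. The Rpl and Ccl groups, at -0.23 (percentile 1.22) and -0.87 (percentile 0), share most genes with the ribosomal and chemokine lists. The ribosomal list lay inside the random range without suffixed probe sets and on B alone. None of the 6 groups was rerun in these ways. Under each of the 5 other scalings these 6 groups stayed below percentile 2.5, although the Rpl median turned to 0.03 under bacterial-control scaling. Of these, no scaling, equal medians and bacterial controls shift all ratios of an array type alike. They leave a percentile less room to move.

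Of the metalloproteinase inhibitors, Timp1 was 6.19-fold lower and Timp2 3.11-fold higher in deficient cells, and Mmp14, a membrane metalloproteinase encoded near Cebpe, stood at 1.08.

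None of the other scalings tried removed the lower chemokine signal. Bacterial-control scaling, which raised the chemokine median most, left it at -0.61, with all 9 genes below 0. The upper 95% bootstrap bound of that median was -0.22. With all genes below 0 that bound could not reach 0, so it adds no support. It holds only the spread between genes. Swapped labels on 1 array type would turn the correlation between types below 0, and its lower 95% bootstrap bound was 0.36, which leaves open a swap on both types. Fewer macrophages in the deficient sample cannot be told apart from lower expression: the macrophage marker median lay 0.55 above that of the chemokines, within the markers' SD of 0.88. The resident macrophage and alternative activation lists were lower too, at -0.42 and -0.97, whereas Csf1r, Ccr2 and Mpeg1 stood at 0.84, 0.97 and 0.66 and the labels give about 30% monocytes in both genotypes. Neutrophil markers were below 0 in 7 of 8 cases (median -0.24, percentile 6.42, mean -0.66). Mesothelial and fibroblast markers were so in 5 of 5 (median -0.57, percentile 3.73). The labels give about 60% neutrophils in both genotypes, and a different share of these cells was not tested. An effect of the genotype within cells, or differences between mice that 1 array per genotype cannot show, may also account for the pattern and were not tested.

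For the higher Apoe and Apoc2, a fault of 1 array is unlikely for Apoe, which was higher by 3.43 log2 units on the other array type as well. More macrophages in the deficient sample would raise macrophage markers together, but the median of the other markers was -0.33, so they showed no common rise. Apoe lay 2.55 above that median, beyond the other markers' SD of 0.72. Apoe was picked for its high ratio, so such a gap was likely in advance and decides little. A different mix of macrophage kinds was not tested. Whether the Apoc2 probes read another transcript cannot be told apart from a true difference, because 0 further Apoc2 probe sets were above the floor on both arrays. The other Apoc2 probe set read 306 in wild-type and 502 in deficient cells, so it showed no rise above the floor. Both Apoe probe sets are of the family type, so shared probes stay open there too.

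A chromosome segment of the targeted strain around Cebpe, carried along in the mixed background, could have made neighbouring genes differ. The 40 measured genes nearest in gene order on assembly GRCm38.p6 had a median absolute log2 ratio of 0.28, at percentile 33.7 of random lists matched on signal. Of these genes 1, Mmp14, was past 2-fold, or 2.5%, against 6.64% of all measured genes, so this test gave no sign of such a segment. The set reached up to 344 gene steps from Cebpe, so a much shorter segment stays open. A longer segment that altered only a minority of its genes stays open too, since a median would hardly show it.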
